A study of Mesocricetus auratus with 14 samples.

How the data were processed

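Liver RNA of 14 golden hamsters' samples (Mesocricetus auratus), all labelled as fed a high-fat diet, was sequenced, 7 samples labelled control and 7 labelled as treated with the compound DC371739. Per the labels' protocols, libraries were made from total RNA; the labels name both a TruSeq and a NEBNext preparation kit for every sample and give no batch or date. Dose, route, duration of treatment, time of tissue collection and sex of the animals are not given in the sources used here. The labels do not say outright that each sample came from a separate animal, so the p-values measure the spread between these samples.

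The authors deposited a table of gene counts and a table of normalized values. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts 2.0.0 and edgeR (version not given) were used; their order and settings, the genome build, the annotation release and the strand setting are not given in the sources used here. Per the file headers, the deposited count table holds whole-number counts per Ensembl gene, with each gene's exon coordinates on named scaffolds and its summed exon length. It has 22283 genes, of which 4781 had a count of 0 in all 14 libraries. It lists genes alone, with no line for unassigned reads. The second deposited table holds FPKM values per library for 10023 genes with a gene symbol, and the authors' log2 fold change, log2 mean CPM, p-value and adjusted p-value for each. From the values, each FPKM equals the count divided by gene length and by 1 constant per library, with a largest relative deviation of 1.3e-07, so that the authors' FPKM are scaled per library. Gene symbols were taken from the authors' table; genes without a symbol are given by identifier. Reads shared between near-identical genes, or between overlapping and antisense genes, cannot be told apart from these counts.

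Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F-test with robust dispersion estimates, TMM scaling and the default expression filter (minimum count of 10), which left 12166 genes, 10011 of them with a symbol. The model held the treatment group alone. Benjamini-Hochberg adjusted p-values under 0.05 were called. Standard errors of log2 fold changes were obtained from the fold change and the square root of its F statistic. Values of single genes are given as CPM, the count as a share of the TMM-scaled library total times 1e+06, as mean ± SD over 7 libraries. Log2 CPM used a prior count of 2.

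Of the Ensembl identifiers, 0 were in the reference table of symbols. Apart from C5ar1, Nr1d1 and 2 genes without a symbol, which were chosen after their values were seen, the genes named in the text followed a rule fixed before the data were examined: Cyp7a1 and further genes in any case; the 10 largest rises and 10 largest falls among genes with a symbol other than a locus number, an adjusted p under 0.05 and a mean log2 CPM of at least 1; and, for each of 29 gene lists, examples from the 4 members of smallest p. Some genes that the rule takes are not reported here. The lists were fixed at the same time. They covered cholesterol synthesis, lipoprotein secretion and clearance, bile acids, fatty acid and triglyceride synthesis, fatty acid oxidation, lipid droplets, targets of hepatocyte transcription factors, gluconeogenesis and insulin response, xenobiotic metabolism, NRF2 targets, unfolded protein response, acute phase, interferon response, extracellular matrix, oxidative phosphorylation, cell cycle, circadian clock, immediate early genes, pericentral and periportal hepatocytes, 7 further sets of cell markers (macrophage, lymphocyte, neutrophil, endothelial, stellate, cholangiocyte and erythroid), other tissues, and sex-linked genes. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Fry tested whether the members of a list moved, on balance, in 1 direction. Its mixed test asked whether members moved in either direction.

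Alternatives fixed in advance were RLE, upper-quartile or no scaling factors, no expression filter or a filter of at least 1 CPM in 7 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, a block on the replicate number, each library left out in turn, and an added limit of 1 on the absolute log2 fold change. After 3 libraries were seen to stand apart, a term for library class (the 3 libraries of highest total count against the other 11) and a fit without those 3 were added, each with the same list tests. No pair of libraries in a group agreed within sampling noise: the lowest chi-square per degree of freedom over 42 pairs was 10.6.

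The test was checked on simulated counts drawn from the real means, dispersions and library sizes. For the comparison of all 14 libraries (12166 genes, 200 of them changed), 36 of 79 genes changed 1.5-fold, 45 of 58 changed 2-fold and 58 of 63 changed 3-fold were recovered, and 9 of 148 calls were false. For the 11 shallower libraries (12249 genes), 39 of 68, 57 of 67 and 60 of 65 were recovered, with 6 false calls among 162. Simulated genes were drawn independently and without library classes, so these shares need not hold for the real libraries.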

Results

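The transcriptome of the liver was measured by RNA sequencing in Syrian golden hamsters on a high-fat diet, a rodent whose lipoprotein metabolism is commonly studied as a model of dyslipidaemia. The study compared 7 samples labelled control with 7 labelled as treated with DC371739, a compound known here by its code name. Libraries held 13672589 to 23948628 counts.

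3 libraries stood apart from the other 11. Control replicates 6 and 7 and DC371739 replicate 7 held 22152239 to 23948628 counts, against 13672589 to 16710097 in the others. Mitochondrial features took 12.6% to 14.4% of their counts, against 7.23% to 9.33%. On the first principal component of the tested genes, which held 33.3% of the variance, they scored 41.6 to 46.8 and the other 11 scored -30.6 to -0.97. The class of deeper libraries held 2 control libraries and 1 DC371739 library, too few for a value of its own. Results are therefore given over all 14 libraries, and the counts of called genes, in total and per list, also with a term for library class and over the 11 shallower libraries (5 control and 6 DC371739). Adjusted p-values of single genes and of lists are over all 14 libraries unless said otherwise.

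**Figure D1:**
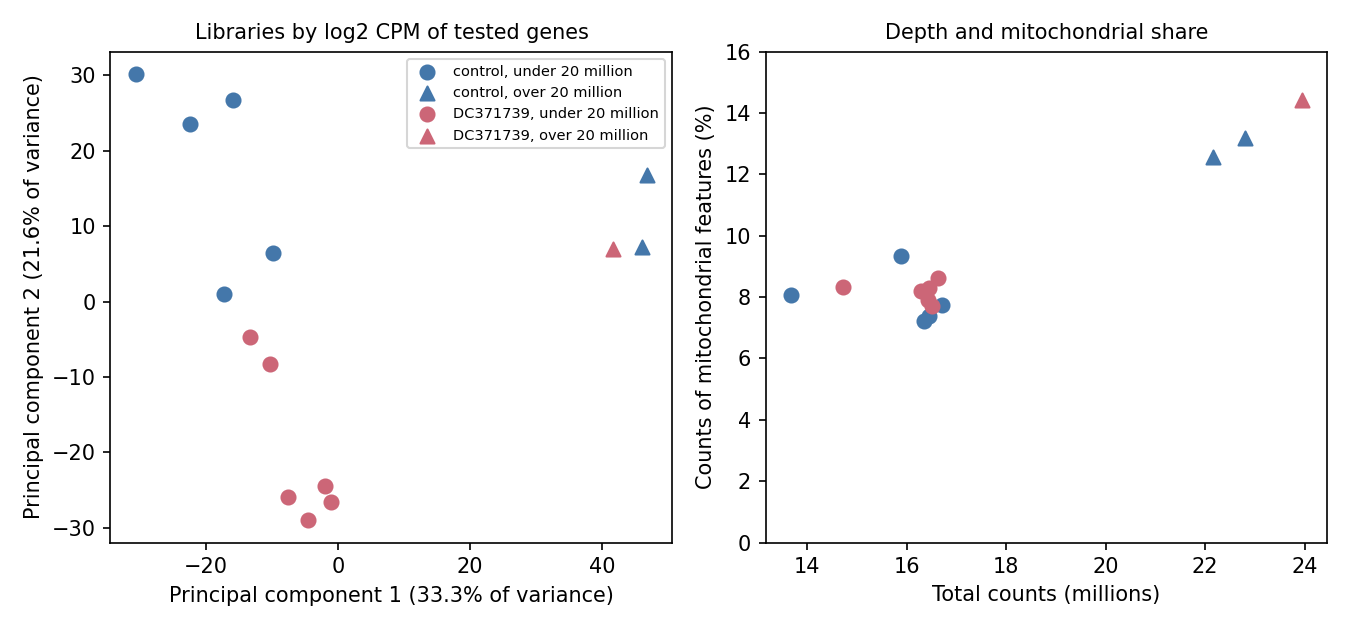
Left, each of the 14 libraries on the first and second principal components of log2 CPM, in arbitrary units; right, total counts against the percentage of counts in mitochondrial features. Colours give the treatment group, and triangles mark the 3 deeper libraries, which lie at 12.6% or more mitochondrial counts.

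The comparison of DC371739 with control asked which liver transcripts differed after treatment. Tgm1, a transglutaminase, rose from 2.92 ± 1.05 to 18.5 ± 10.1 CPM (SD, n = 7 each), a log2 fold change of 2.66 (SE 0.36). Tlr2, a receptor for bacterial lipoproteins, rose by 1.67 (SE 0.31) and Timp1, an inhibitor of matrix metalloproteinases, by 1.36 (SE 0.29). Lower genes included G0s2, an inhibitor of adipose triglyceride lipase, which fell from 112 ± 53.1 to 36.7 ± 13.7 CPM, a log2 change of -1.61 (SE 0.31).

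Of 12166 genes tested with edgeR's quasi-likelihood test, 225 passed an adjusted p of 0.05, 151 higher and 74 lower with DC371739; 186 of them had a symbol. Upper-quartile scaling gave 223 higher and 65 lower, and library size alone 124 and 36. DESeq2 called 848 genes (517 higher, 331 lower) and limma-voom with sample quality weights 2727 (1406 higher, 1321 lower). A block on the replicate number left 8 (6 higher, 2 lower), and an added limit of 1 on the absolute log2 fold change 47 (40 higher, 7 lower). With the library class term 1499 genes passed (684 higher, 815 lower), and over the 11 shallower libraries 2635 of 12249 (1353 higher, 1282 lower). All 225 genes passed with the same sign in both of these fits. Both reuse libraries in which the 225 were called, and more genes passed in each, so this is no independent support. The count of 225 moved by more than 1.5 times without any of 10 libraries: it was 106, 73, 53, 63 and 542 without control replicates 1, 2, 3, 5 and 7, and 51, 25, 77, 25 and 1069 without DC371739 replicates 2, 3, 5, 6 and 7. The count of 2635 over the shallower libraries fell to 1747 without control replicate 2 (a change of over 1.5 times) and to 1624 without control replicate 5.

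Beside Tgm1, Tlr2 and Timp1, the largest rises included those of Ace, the angiotensin-converting enzyme (log2 fold change 1.54, SE 0.30), Rab7b (1.53, SE 0.33), Rad54l2 (1.41, SE 0.24), Steap4, a metalloreductase (1.40, SE 0.29), Tnfaip3, an inhibitor of NF-kB signalling (1.30, SE 0.31), and Cpm, the gene of carboxypeptidase M, which went from 1.19 ± 0.85 to 3.47 ± 1.21 CPM. Steap4 was the most abundant of these, at 85.8 ± 20.6 CPM in control and 226 ± 113 CPM in DC371739 samples. Adjusted p ranged from 0.00700 for Tgm1 to 0.0494 for Cpm. All 7 DC371739 libraries lay above the control median for each of these genes but Tnfaip3, for which 6 of 7 did. In the deeper DC371739 replicate 7, Tlr2, Steap4, Cpm, Rad54l2 and Tnfaip3 lay within the control range, and Tgm1, Timp1, Ace and Rab7b above it. In DC371739 replicate 4, Ace, Rab7b, Steap4, Timp1 and Tnfaip3 lay within that range. The smallest p of all genes belonged to C5ar1, the receptor of complement fragment C5a, chosen after its values were seen (5.72 ± 0.76 against 12.7 ± 2.71 CPM, adjusted p = 0.00456).

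Beside G0s2, the largest falls included those of Gadd45g, a stress-response gene (-1.54, SE 0.35), Cry1, a repressor of the circadian clock (-1.40, SE 0.32), Sgk1, a kinase induced by glucocorticoids (-1.28, SE 0.22), Dusp6, a phosphatase of ERK (-1.10, SE 0.16), Jund (-0.99, SE 0.22), the thiamine transporter Slc19a2 (-0.95, SE 0.18), the transcription factor Jun (-0.95, SE 0.23) and Lonrf3 (-0.95, SE 0.23). Sgk1 went from 190 ± 57.9 to 78.3 ± 24.9 CPM. For each of these genes, all 7 DC371739 libraries lay below the control median. In both of the 2 deeper control libraries G0s2, Cry1 and Lonrf3 lay within the range of the DC371739 samples. G0s2 stood at 53.6 and 46.1 CPM in control replicates 6 and 7, against 95.8 to 187 CPM in the other 5 controls. Cry1 stood at 9.24 and 6.97 CPM, against 14.2 to 30.5 CPM, and Lonrf3 at 6.77 and 7.06 CPM, against 8.40 to 14.6 CPM. Whether the treatment difference itself differed between the library classes was not tested.

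Tgm1, Rad54l2, Sgk1 and Dusp6 passed whichever single library was left out. All 20 genes that the rule takes by size of change passed with the library class term and over the 11 shallower libraries. Both fits reuse libraries in which the 20 were chosen. For 15 of the 20 the call was lost without at least 1 library, with an adjusted p of up to 0.107 (Tnfaip3 without DC371739 replicate 3). Of the 20, the number that no longer passed was 8, 12, 11, 7, 10 and 4 without control replicates 1 to 6, and 6, 13, 15, 4, 9 and 14 without DC371739 replicates 1 to 6; none was lost without replicate 7 of either group. Of the called list examples outside these 20, Laptm5, Ctss and Mt2a also passed whichever library was left out, and Mpeg1, Myh11, Atf4 and Klb did not.

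**Figure D2:**
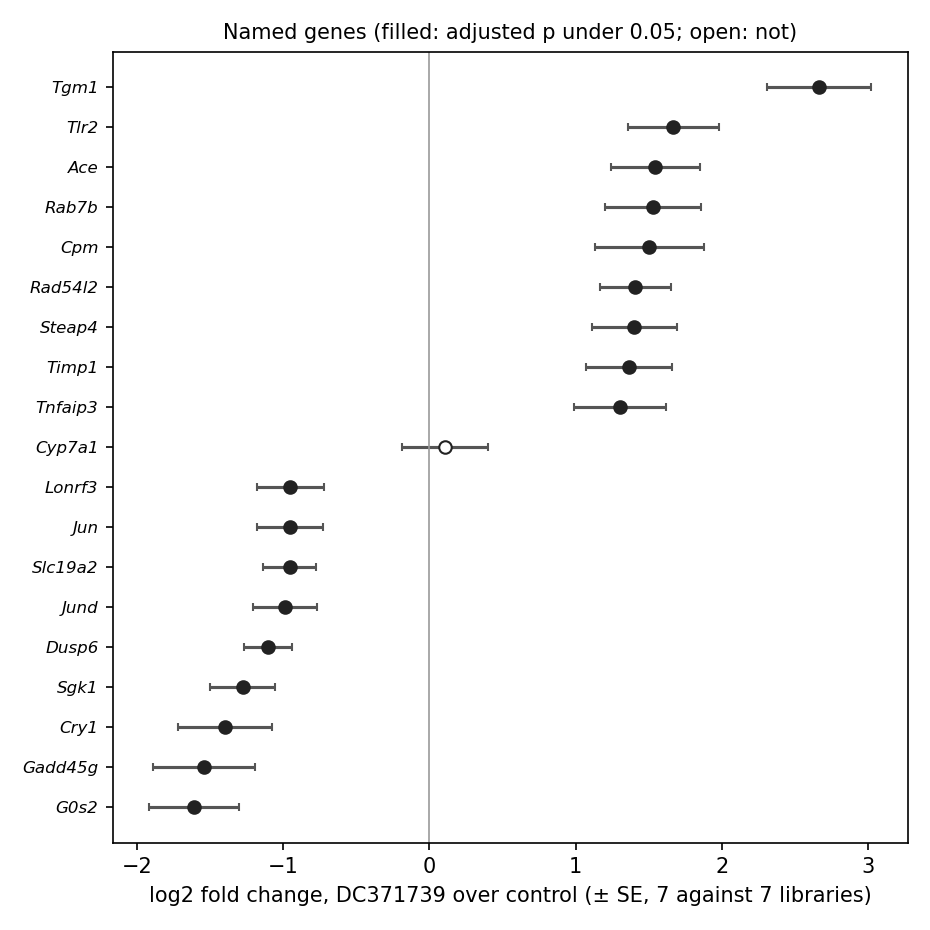
Log2 fold change of DC371739 over control with its standard error for named genes, from edgeR's fit of 7 against 7 libraries; filled points passed an adjusted p of 0.05 and the open point, Cyp7a1, did not. The points run from -1.61 for G0s2 to 2.66 for Tgm1.

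Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 35.5 ± 9.41 CPM in control and 38.2 ± 19.5 CPM in DC371739 samples (log2 change 0.11, SE 0.29, adjusted p = 0.877). Its sign flipped with limma on FPKM and not under another scaling of the counts. Cyp7a1 lay below the control median in 4 of 7 DC371739 libraries and above it in 3. Its highest value was 66.2 CPM in DC371739 replicate 5, so its sign rests on few libraries.

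In the count table's coordinates, whose build is not given in the sources used here, Tgm1 (ENSMAUG00000010151) spans 2363786 to 2376344 of KB708321.1 and G0s2 (ENSMAUG00000010676) 1853534 to 1854504 of KB708265.1. Counts cover the summed exons of each gene. Among the 39 called genes without a symbol, of which 2 were chosen after their values were seen, ENSMAUG00000013739 (KB708214.1, 2156678 to 2191504) had a log2 fold change of 0.79 and ENSMAUG00000003989 (KB708156.1, 5589398 to 5606852) of -0.64.

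Of 27 gene lists with at least 3 tested members, 8 passed camera's test at the preset correlation. None passed with an estimated correlation (3 at an unadjusted p under 0.05) or with fry (9 unadjusted). With the library class term 9 passed at the preset correlation, 0 with an estimated one and 3 with fry, namely macrophage markers and extracellular matrix genes, which were higher, and the circadian clock list, which was lower (each adjusted p = 0.0453). Over the 11 shallower libraries the numbers were 8, 0 and 0. Over all 14 libraries 43 of 100 splits gave as many lists at the preset correlation, the real one included. Of 106 genes taken as examples from the lists, as their members of smallest p, 16 passed over all 14 libraries. Of the other 90, 33 passed with the class term, 50 over the 11 shallower libraries and 39 in neither fit. Since the examples were chosen by p in the same libraries, these numbers cannot be set against the share over all genes. The erythroid list had 2 tested members and the sex-linked list 0. Over all genes 1499 of 12166 passed with the class term and 2635 of 12249 over the shallower libraries. The counts of called members given below for these fits were not tested against that share. A number near it does not single out a list.

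Of 21 macrophage markers, 3 rose, none fell and 18 did not pass; adjusted over the list alone, 13 rose. Laptm5 (log2 fold change 0.70, SE 0.11), the protease Ctss (0.77, SE 0.13) and the pore-forming Mpeg1 (0.80, SE 0.16) were the 3, with Ctss going from 42.4 ± 4.94 to 72.6 ± 14.9 CPM. Mpeg1 did not pass without control replicate 3 or 5 or DC371739 replicate 2, 3, 5 or 6 (adjusted p up to 0.0674). Timd4 stood at 0.50 (adjusted p = 0.0512). Log2 fold changes over all 14 libraries were positive for 17 of the 21 and negative for 4. With the library class term 11 of the 21 rose, and over the 11 shallower libraries 9 did. None fell in either. The list had an adjusted p of 1.28e-08 at the preset correlation and 0.363 with an estimated correlation.

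Extracellular matrix genes had a median log2 fold change of 0.40, and 27 of 28 were positive; Timp1 passed, and 10 rose adjusted over the list alone. In the fit with the class term 7 of the 28 rose, as did 7 over the shallower libraries, and none fell in either. The matrix list's mean log2 CPM was 4.43, 4.26 and 4.28 in DC371739 replicates 1, 4 and 7, within the control range of 3.91 to 4.45. It stood at 4.49 to 5.02 in DC371739 replicates 2, 3, 5 and 6. Col4a2 (0.80), Col1a2 (0.58) and Col3a1 (0.52) had adjusted p of 0.0708, 0.0831 and 0.0944. The list's adjusted p was 1.28e-08, and 0.363 with an estimated correlation. Stellate and fibroblast markers, 5 of whose 21 tested members stand in another list, had a median of 0.29; Myh11, smooth muscle myosin, rose (0.53, SE 0.11) and 3 rose adjusted over the list alone (adjusted p = 0.000176, and 0.363 with an estimated correlation). Myh11 did not pass without control replicate 1, 2 or 3 or DC371739 replicate 2, 3 or 6 (adjusted p up to 0.0691). Of these markers 2 rose with the class term and 3 over the shallower libraries. Acute phase and cytokine genes had a median of 0.33 with 22 of 23 positive; Steap4 passed, 8 rose adjusted over the list alone, and Tnf (1.08), Stat3 (0.75) and Ccl2 (1.16) had adjusted p of 0.0609, 0.0681 and 0.0708 (list adjusted p = 4.51e-06, and 0.459 with an estimated correlation). Of this list 4 rose with the class term and 7 over the shallower libraries, and none fell. Its mean log2 CPM was 7.73, 7.29 and 7.33 in DC371739 replicates 1, 4 and 7, within the control range of 7.12 to 7.74. It stood at 8.07 to 8.13 in DC371739 replicates 2, 3, 5 and 6. Lymphocyte markers had a median of 0.29, no called member and 1, Prf1 (1.08), adjusted over the list alone; the list's adjusted p was 0.0228, and 0.647 with an estimated correlation, and over the 11 shallower libraries it was 0.280. Of its 14 genes 2 rose with the class term and 2 over the shallower libraries. Endothelial (median 0.10, adjusted p = 0.0853), cholangiocyte (0.16, 0.635) and neutrophil markers (0.26 over 4 genes, 0.113) did not pass and had no called member. With the class term 2 endothelial markers and 1 neutrophil marker rose, and over the shallower libraries 5 endothelial, 2 cholangiocyte and 1 neutrophil marker rose and 1 cholangiocyte marker fell.

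Of 23 immediate early genes, which cells induce within minutes of a stimulus, 4 fell (Dusp6, Jund, Gadd45g and Jun), none rose and 19 did not pass. Log2 fold changes were negative for 18 and positive for 5, and adjusted over the list alone 11 fell and 1 rose. With the class term 6 fell and none rose, and over the shallower libraries 7 fell and 1 rose. Their median was -0.73, and the list's adjusted p was 6.59e-08 at the preset correlation, 0.363 with an estimated correlation and 0.0641 with fry. Nuclear-encoded oxidative phosphorylation genes had a median of -0.19 with 28 of 32 negative. Their mean log2 CPM was 6.96, 6.95 and 7.06 in DC371739 replicates 1, 4 and 7, within the control range of 6.82 to 7.12. It stood at 6.65 to 6.79 in DC371739 replicates 2, 3, 5 and 6. No member was called over all 14 libraries, Ndufa2 coming nearest (-0.64, adjusted p = 0.0512); with the class term 1 rose and 2 fell, and over the shallower libraries 1 rose and 9 fell. Adjusted over the list alone, 1 fell over all 14; the list's adjusted p was 6.56e-06, and 0.647 with an estimated correlation. In the circadian clock list (adjusted p = 0.564) members went both ways, and 3 rose and 4 fell adjusted over the list alone. Both with the class term and over the shallower libraries 4 of the 14 fell and none rose. Cry1 fell, Arntl, a core activator of the clock, was at 22.2 ± 9.09 and 11.1 ± 2.71 CPM (adjusted p = 0.0551), and Nfil3 and Rora had log2 changes of -0.67 (0.0778) and -0.40 (0.0608). The list's median was 0.02 and its mean -0.08.

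Genes of gluconeogenesis and insulin response had a median of 0.30, 17 of 23 being positive (adjusted p = 0.00380, and 0.459 with an estimated correlation). Over all 14 libraries none of the 23 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell. With the class term 3 rose and 2 fell, and over the 11 shallower libraries 11 rose and 2 fell. Pck1, which drives gluconeogenesis, was at 417 ± 245 and 974 ± 352 CPM (log2 change 1.22, adjusted p = 0.0963), Irs2 at 0.90 (0.0839) and Slc37a4, the glucose 6-phosphate transporter, at 0.45 (0.0696). 9 of the 23 stand in another list.

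**Figure D3:**
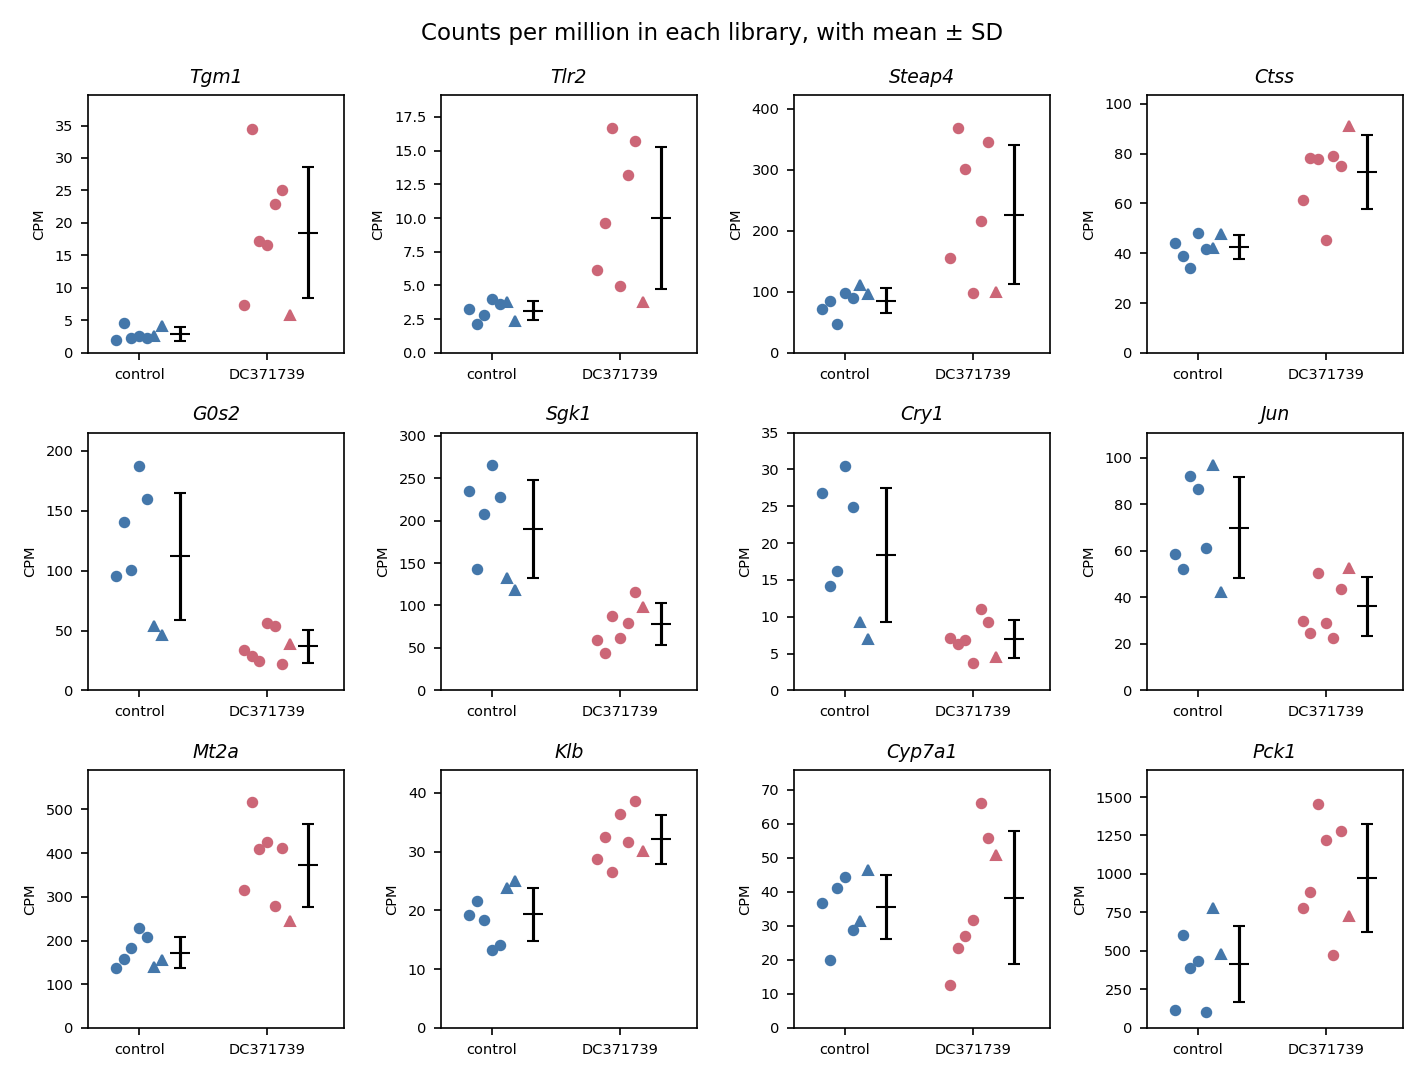
CPM per library of 12 genes in the 7 control and 7 DC371739 libraries, with the mean and SD beside each group; triangles are the 3 deeper libraries. Tgm1 lies at 2.92 CPM on average in control and 18.5 CPM in DC371739 samples.

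Lists of lipid metabolism did not pass as wholes over all 14 libraries, with the class term or over the shallower ones. These tests were for a shift in 1 direction. Fry's mixed test over all 14 libraries gave them unadjusted p from 0.000290 (lipoprotein secretion and clearance) to 0.0507 (fatty acid and triglyceride synthesis). Its smallest p of any list was 7.11e-06, for NRF2 targets. The mixed test does not set a list against other genes, and 2476 of all 12166 genes had an unadjusted p under 0.05. It thus does not single out the lipid lists. Periportal (0.0217), endothelial (0.0290) and lymphocyte markers (0.0468) also lay under 0.05 in it, while interferon (0.486) and cell cycle genes (0.880) did not. Cholesterol synthesis had a median of -0.08 over 20 genes and no called member (adjusted p = 0.528), with Insig1 at -0.71 (0.0968), Msmo1 at -0.52 (0.107) and Srebf2 at 0.52 (0.109). In lipoprotein secretion and clearance (26 genes, adjusted p = 0.967) Angptl8 was at -0.62 (0.0635) and the endothelial lipase Lipg at 1.79 (0.0656), 1 higher and 1 lower when adjusted over the list alone, and none was called over all genes. Of 23 genes of bile acid synthesis and transport (adjusted p = 0.967), Klb, the FGF19 co-receptor, rose (0.73, SE 0.14), and did not pass without control replicate 3 or DC371739 replicate 2 or 6 (adjusted p up to 0.0584). Fatty acid and triglyceride synthesis (22 genes, adjusted p = 0.736) had 1 called member, which fell, with Lpin1 at 1.35 (0.0635) and Dgat2 at -0.34 (0.1004). In fatty acid oxidation (26 genes, adjusted p = 0.885) Fabp1 was at -0.42 (0.0540), Cpt1a at 0.81 (0.0709) and Ppara at 0.75 (0.0734), with no called member. In the lipid droplet list (15 genes, adjusted p = 0.967) G0s2 fell, and Mgll was at 0.60 (0.123). Of targets of hepatocyte transcription factors (33 genes, adjusted p = 0.967) none passed over all 14 libraries; Hnf4a was at 0.48 (0.0795) and Cebpa at -0.65 (0.0839). The fit with the class term called 0 genes higher and 3 lower in cholesterol synthesis, 4 and 3 in lipoprotein secretion and clearance, 1 and 2 in bile acid synthesis and transport, 0 and 4 in fatty acid and triglyceride synthesis, 3 and 1 in fatty acid oxidation, 1 and 1 in the lipid droplet list and 1 and 1 among the transcription factor targets. Over the 11 shallower libraries these numbers were, in the same order, 1 and 2, 8 and 4, 2 and 2, 2 and 5, 3 and 1, 3 and 2, and 4 and 3 (of 32 tested).

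Mt2a, a metallothionein, rose from 172 ± 35.5 to 372 ± 95.8 CPM (log2 fold change 1.11, SE 0.17) within the NRF2 and oxidative stress list (21 genes, adjusted p = 0.763), where Sod2 stood at 0.47 (0.0551). In that list 2 rose and 1 fell with the class term, and 4 rose and 2 fell over the shallower libraries. Atf4, the transcription factor of the integrated stress response, fell (-0.43, SE 0.08) within the unfolded protein list (23 genes, adjusted p = 0.1003), where Manf was at -0.51 (0.0674). Atf4 did not pass without control replicate 3 or 5 or DC371739 replicate 3 or 6 (adjusted p up to 0.0575). With the library class term the list's adjusted p was 0.0416, and 0.664 with an estimated correlation, and 6 of its genes fell. Over the shallower libraries it was 0.0347, and 0.702 with an estimated correlation, and 2 rose and 6 fell. Over all 14 libraries no member passed in xenobiotic metabolism (27 genes, adjusted p = 0.721), interferon response (20, 0.605), cell cycle (27, 0.782), pericentral (17, 0.605) or periportal markers (22, 0.511), or the 4 tested markers of pancreas, adipose tissue and muscle (0.605). Of the 50 symbols fixed for xenobiotic metabolism, some of them alternative names, 27 were tested. No tested gene carried the symbol Cyp1a1, Cyp2b6, Cyp2b10, Cyp3a4 or Cyp3a11, so the list does not bear on those inducible enzymes. With the class term 2 xenobiotic genes and 1 periportal marker rose. Over the shallower libraries 5 xenobiotic genes and 3 periportal markers rose, and 1 xenobiotic gene and 1 pericentral marker fell. The interferon, cell cycle and other-tissue lists had no called member in either fit.

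**Figure D4:**
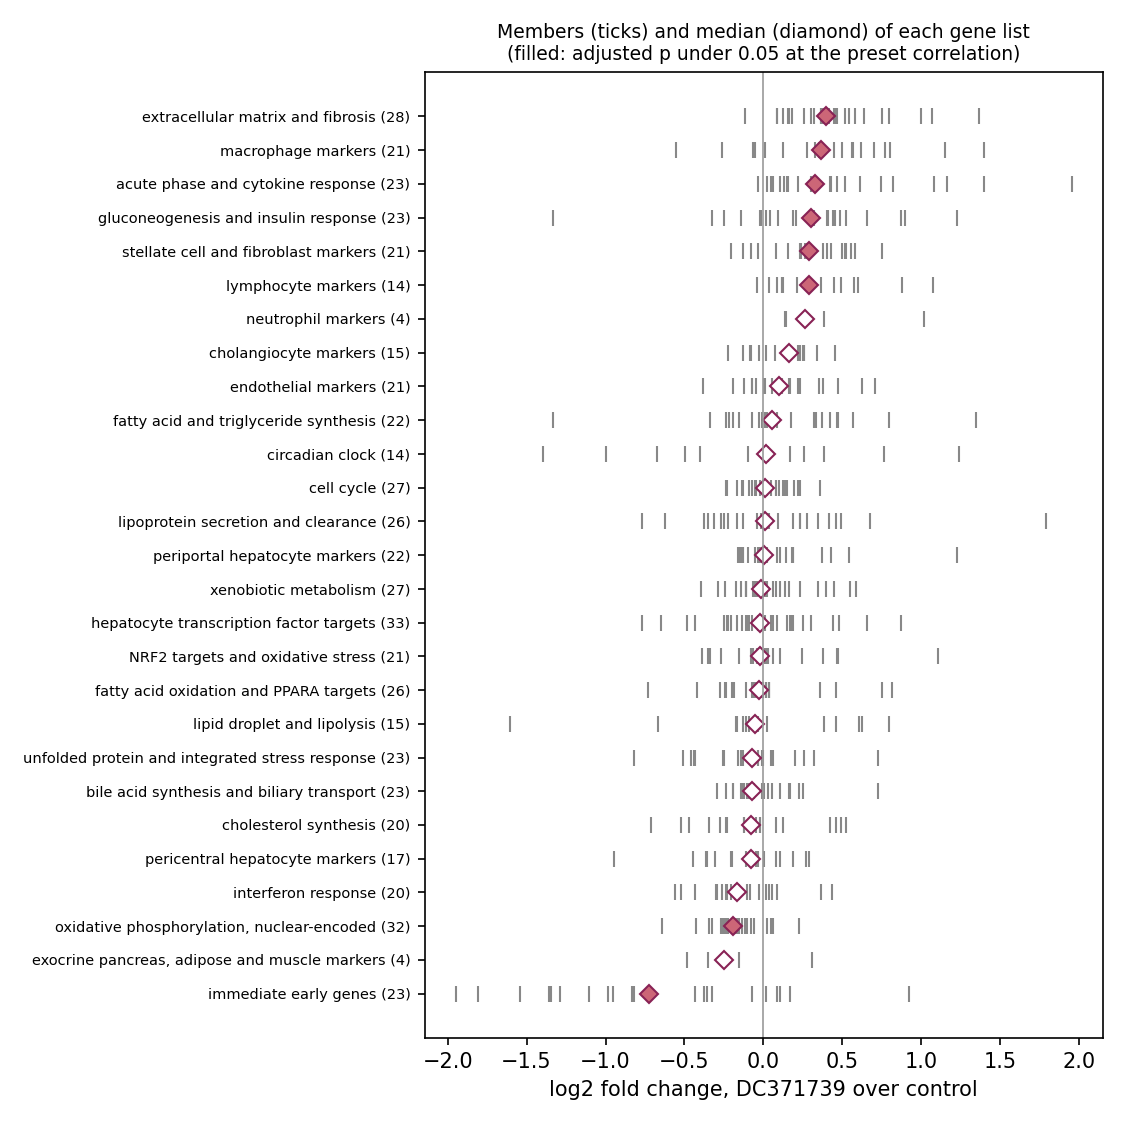
Log2 fold change of DC371739 over control for the members of 27 gene lists (ticks; the number tested in parentheses) and each list's median (diamonds). Filled diamonds mark the 8 lists with an adjusted p under 0.05 at the preset correlation, from -0.73 for immediate early genes to 0.40 for extracellular matrix; none passed with an estimated correlation.

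In the authors' deposited table of 10023 genes, 210 had an adjusted p under 0.05, 140 higher and 70 lower with DC371739. Of these, 185 also passed here. Across 10011 genes, which are not independent replicates, the log2 fold changes in the authors' deposited table and those computed here had r = 0.99999.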

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

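Chosen only after the result, or values that imply it, had been seen were the tests of the correlation between library classes, of the cell types, of the macrophage and immediate early lists without the 3 deeper libraries, and all counts of splits of the samples. In 252 groups of 7 libraries, 16 had a sample whose gap to its neighbour, as a share of the group's range, exceeded Dixon's 95% critical value; about 1 in 20 would by chance.

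DC371739 replicate 7 was far from the other 6 of its group in total counts (23948628, next 16627596; 23.9 and 16.6 in units of 1e+06), in mitochondrial share (14.4%, next 8.63%) and in the share of counts in genes without a symbol (27.9%, next 22.2%). In the same library Mgll was low (59.1 CPM, next 125) and Hilpda high (24.6 CPM, next 11.8). In DC371739 replicate 2, Lipg (12.02 CPM, next 4.74) and Lpin1 (115 CPM, next 32.6) were high. Laptm5 was low in DC371739 replicate 4 (34.9 CPM, next 46.5), and Alas2 high in DC371739 replicate 5 (28.1 CPM, next 12.4). Among control libraries, the far samples were replicate 6 for Insig1 (265 CPM, next 175), replicate 2 for Lipg (3.36 CPM, next 1.53) and Apoc4 (1154 CPM, next 883), replicate 4 for Abcc4 (4.95 CPM), replicate 1 for Psmb9 (180 CPM, next 85.7) and Psmb8 (254 CPM, next 145), and replicate 3 for Cdc20 (9.48 CPM, next 5.90).

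The 3 deeper libraries lay 42.6 units beyond the nearest other library on the first principal component. Depth alone is argued against, since the gap was 43.3 after thinning them to 16432805 counts, and so is a few abundant genes taking the counts, since it was 42.2 without mitochondrial features and the 100 most abundant genes. The deeper-minus-other difference per gene correlated between control and DC371739, from separate libraries, at r = 0.644 across 12166 genes, which are not independent replicates. Since the 3 were grouped for standing apart together, any difference they share would give such a correlation, which cannot tell causes apart. A difference in library preparation or sequencing shared by the 3 may be a candidate explanation, but the labels name no batch. A difference between animals or in time of collection shared by the 3 stays open and untested beside it.

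A count of changed genes as high as the real one was rare among splits but occurred, so chance was not excluded. Of 100 splits (of 1716), 2 gave 225 or more, the real one included. The other was the highest, at 639, and put all 3 deeper libraries on 1 side. That alone does not account for its count: of the 17 further splits that did so, 15 gave 0 genes and the highest gave 10. A count above the real one points to a structure of the samples, which was not identified. For genes higher and genes lower it was also 2 of 100 each, with 474 as the highest of the others; since the sides of these splits have no order, the larger of their 2 directions was counted for both. With the library class term, within which splits were drawn, 1 of 100 gave 1499 or more (highest other 252), and over the 11 shallower libraries 1 of 100 gave 2635 or more (highest other 1683, a split that exchanged 1 pair of libraries). For the number of gene lists chance could not be excluded: 43 of 100 splits gave 8 or more (highest other 19), 43 with the class term gave 9 or more (highest other 20), and 56 over the 11 libraries gave 8 or more (highest other 17).

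Macrophage, matrix and acute phase lists were higher with DC371739 at the preset correlation and not with an estimated one. In DC371739 replicates 1, 4 and 7 the mean log2 CPM of the matrix and acute phase lists lay within the control range. The 3 deeper libraries alone are argued against for the macrophage list: without them its mean log2 CPM was still higher by 0.44 (two-sided exact permutation p = 0.0152; 0.123 adjusted over 27 lists). A lower share of hepatocytes would raise markers of other cell types alike; over macrophage, lymphocyte, endothelial, stellate and cholangiocyte markers, the SD of the 5 differences was 0.15, as large in relabelled libraries with an exact permutation p of 0.101, so that this explanation and a change of the macrophages themselves cannot be told apart with these libraries. A response to DC371739 stays open beside it.

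Immediate early genes were lower at the preset correlation and not with an estimated one (adjusted p = 0.363) or with fry (0.0641), and the clock score, whose arms were drawn up after the values of its genes were seen, was higher by 0.95. The 3 deeper libraries alone are argued against for the immediate early list, which was lower by 0.69 without them (two-sided exact permutation p = 0.0325; 0.123 adjusted over 27 lists). Time or order of tissue collection, not given in the sources used here, would tie both sets of genes within a group; over the 11 shallower libraries, with group means removed, Pearson's r was 0.0171 (permutation p = 0.962) and Spearman's rho -0.118 (permutation p = 0.749), the only relation computed. The approximate 95% interval of r ran from -0.654 to 0.674, and r was 0.537 without the 2 libraries farthest from the median, so collection time and treatment cannot be told apart here.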

How the results depend on the processing

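The library class term, the fit without the 3 deeper libraries and the list tests within them were chosen after seeing the data. The counts of changed, higher and lower genes stayed within 1.5 times of 225, 151 and 74 with RLE or upper-quartile scaling, the stricter filter and limma on FPKM; without scaling factors or without a filter the lower genes were 36 and 46. DESeq2 called 848 (517 higher, 331 lower), limma-voom with quality weights 2727 (1406, 1321), the class term 1499 (684, 815) and the fit without the deeper libraries 2635 (1353, 1282). An added limit on the fold change left 47 (40, 7). Leaving out 1 library gave 25 to 1069 changed, 18 to 615 higher and 7 to 454 lower genes, and 7 to 10 lists. With a replicate block 8 genes passed (6 higher, 2 lower). The labels do not say whether same-numbered libraries are paired. Same-numbered libraries correlated at -0.13 to 0.55, and only 1 of 7 controls correlated best with its own number. These correlations cannot rule out a pairing, since library class enters them. The deeper control replicates 6 and 7 both correlated best with the deeper DC371739 replicate 7. The number of lists, 8, was 7 to 9 under every scaling, filter and block, and 0 with an estimated correlation or with fry. Under the class term it was 9, 0 with an estimated correlation and 3 with fry, and without the deeper libraries 8, 0 and 0. Of 3301 values of named genes under alternatives, 2862 kept their side of the threshold, 172 lost and 267 gained a call; 27 changed sign, none of them in a gene that passed with all 14 libraries. Of 756 values of lists, 692 kept their side, 53 lost and 11 gained a call, and 63 changed sign. Limma-voom gave the 3 deeper libraries quality weights of 0.244, 0.253 and 0.291, against 0.965 to 1.82 for the others. The common coefficient of variation between libraries in edgeR was 0.225 over all 14. It was 0.161 with the class term and 0.156 without the deeper libraries, so the spread was smaller in these 2 fits. Beyond that, the cause of the differences was not tested. Of simulated genes changed 1.5-fold, 45.6% were recovered over all 14 libraries and 57.4% over the 11 shallower ones. Changes of this size in single genes may thus often have been missed. Whether depth or the spread between libraries limits this was not tested. DESeq2, limma-voom and limma on FPKM gave no list test.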

Other observations

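Both tests in this part, of the clock score and of the mean of each list, were chosen after the results of single genes and lists had been seen. Beside the fall of Cry1, Nr1d1, a repressor of the clock chosen after its values were seen, was at 46.9 ± 20.1 CPM in control and 79.8 ± 34.5 CPM in DC371739 samples (adjusted p = 0.157). The mean log2 CPM of 7 genes of the negative arm and output minus that of 6 genes of the positive arm and its repressors was higher by 0.95 over all 14 libraries (two-sided exact permutation p = 0.00175) and by 1.105 over the 11 shallower ones (p = 0.00216). Because the genes were picked after the single-gene values were known, these p-values are not a valid test of the shift and are no independent evidence of it.

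Permuting the group labels of the mean log2 CPM of each list gave 8 of 27 lists with an unadjusted p under 0.05 over all 14 libraries, 9 within library class and 9 over the 11 shallower libraries; 0 passed after adjustment in each. The smallest adjusted p over all 14 libraries was 0.0629. Camera at the preset correlation called 8, 9 and 8 lists in the same libraries, 0 in each with an estimated correlation, and fry called 0, 3 and 0.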
